A study of Mus musculus with 16 samples.

How the data were processed

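Gonadal white adipose tissue, the fat pad that lies against the epididymis in male mice, was profiled on Affymetrix whole-transcript arrays in 16 samples from male C57BL/6 mice aged 3 to 4 months. Per the labels, 8 samples came from mice with free access to food and 8 from mice fasted for 16 hours, and tissue was taken in the morning. Per the labels' protocols, total RNA was column-purified, checked for intact ribosomal bands, and labelled from 100 ng per sample. The deposited values are on a log2 scale, and RMA is named in the submitters' processing notes, a method that corrects background, normalizes between arrays and summarises the probes of a probe set to 1 value. Its version, the software and any filter on probe sets are not given in the sources used here. The log2 scale was read from the values, which lay between 0.99 and 13.2, with array medians between 3.60 and 3.69. Because RMA sets the arrays to a shared distribution, a shift of most transcripts in 1 direction would not be visible, and changes are relative to the other transcripts on the array. Background signal and probe saturation compress the log2 fold changes of the dimmest and brightest genes. No scan date or other batch was given in the sources used here, so none was modelled. The number of arrays limits the precision. The labels do not state that each sample came from a separate mouse, so p-values measure the spread between these samples.

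The value table held 41345 probe sets. The platform annotation given with it listed 25335 of them, 23521 with 1 gene symbol and 1814 with several, and the remaining 16010 were unnamed here. Of the 23521 probe sets with 1 symbol, 23328 had a gene ID in the RefSeq gene table of assembly GRCm38.p6, and 0 of these carried another symbol there. Only probe sets with 1 symbol were used. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over the 16 arrays was taken, which left 22180 genes. No array pair was identical, and correlations between arrays over all genes lay between 0.966 and 0.993.

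Fasted and fed samples were compared with limma 3.58.1 in R 4.3.3 (lmFit with group as the only term, then eBayes with default settings) on the deposited log2 values without further normalization or filtering. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes. Fold changes are fasted over fed for rises and fed over fasted for falls, and errors of log2 fold changes are moderated standard errors (SE). On simulated data with the spread of the real genes, 61.2% of 67 changes of 0.5 on the log2 scale, 98.5% of 67 changes of 1 and 100% of 66 changes of 2 were recovered, with 12 false calls among the other genes. Far fewer genes were changed there than were called in the real arrays, so these shares need not hold for the real arrays.

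The groups, the test, 23 pathway lists, 15 cell type lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma, two-sided, preset correlation between genes of 0.01), with adjustment over the lists of each kind, and a list needed at least 5 measured members, which the red blood cell list did not have. Of 561 pathway entries 518 were measured, and of 208 cell type entries 185. On simulated data, camera called the 1 shifted list and 0 of 50 unshifted lists. The simulated genes were drawn independently, so this could not show false calls from correlated genes. In the real arrays the preset correlation was permissive, so each list call is given with its adjusted p under a correlation estimated from the list itself. The named genes were the 12 largest rises and 12 largest falls among called genes with ordinary symbols, up to 3 called members of each pathway list and up to 2 of each cell type list by size of change, or the member with the lowest p where none was called, and a fixed panel of 20 genes, 1 of which is not reported here. Genes outside this rule are named only where they make up a small count or a pattern seen in the arrays, and are then said to have been chosen after their values were seen.

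Alternatives were a filter on dim genes (a linear value of at least 20 in at least 8 arrays, or the upper part by mean), subtraction of array medians, cyclic loess, a repeat of quantile normalization, eBayes with trend and robust settings, array weights, the replicate number as a block, each array left out in turn, all probe sets, the lowest probe set of each gene, an exact rank sum test, stricter thresholds, an estimated correlation, the rotation test fry, and lists without shared genes. Leaving out 3 arrays that stood apart, and adding the mean of a list of liver transcripts as a covariate, were chosen after seeing the data, as were the lists of motile cilia, liver and imprinted genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.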

Results

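Gene expression in gonadal white adipose tissue was compared between 8 fed samples and 8 samples from mice fasted for 16 hours, to find which transcripts change in this fat depot when food is withdrawn. All 16 arrays had similar value distributions, and 22180 genes were tested.

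Fasting separated the arrays along the first principal component, which held 29.4% of the variance. The fed arrays lay between -25.7 and -21.7 and the fasted arrays between 12.8 and 30.7. The second component, with 17.9% of the variance, set apart fed replicate 2 at 53.0 and fasted replicate 7 at 37.1. The third, with 7.91%, set apart fed replicate 3 at 34.9. In both fed replicate 2 and fasted replicate 7, transcripts of ciliated epithelium were high, with a median excess over the rest of their group of 1.57 and 1.11 on the log2 scale for 25 motile cilia genes. The mean log2 level of 19 liver transcripts ranged from 4.54 to 6.94 across the arrays, and was highest in fed replicates 3, 2 and 4, at 6.94, 6.66 and 6.59.

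**Figure D1:**
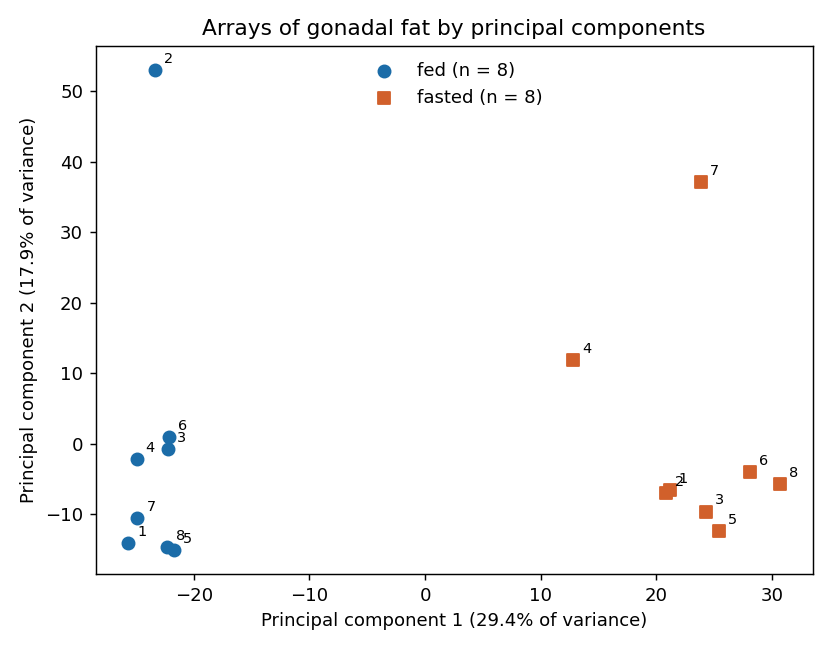
Principal components 1 and 2 of the 16 arrays over 22180 genes, with each point an array numbered by its replicate. Fed arrays (circles) and fasted arrays (squares) lie on opposite sides of component 1, and fed replicate 2 and fasted replicate 7 stand apart on component 2.

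Withdrawal of food raised Pdk4, the kinase that switches off pyruvate dehydrogenase, by 3.32 on the log2 scale (SE 0.094), from 7.37 ± 0.22 to 10.69 ± 0.14 on the log2 scale (SD, n = 8 per group; limma adjusted p = 3.56e-14). The largest rise was that of Zim1, an imprinted zinc finger gene, which went from 4.44 ± 0.29 to 8.96 ± 0.24, a 23.0-fold difference (adjusted p = 3.56e-14). The orphan nuclear receptor Nr4a3 rose by 3.46 on the log2 scale (SE 0.23), the pantetheinase Vnn1 9.39-fold, the retinol-binding protein Rbp7 8.82-fold, the mTORC1 inhibitor Ddit4 8.46-fold and the transcription factor Irf4 8.31-fold. Gprin3, Depp1 and Ccn5 rose 7.59-fold, 5.81-fold and 5.47-fold. Acta1, the skeletal form of actin, rose 6.35-fold while Myl1, a myosin light chain of fast muscle, fell by 1.35 on the log2 scale (SE 0.15). In each of these genes the 8 fasted arrays did not overlap the 8 fed arrays.

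Cyp4a14, a fatty acid hydroxylase that is well known from fasted liver, had a mean 11.4-fold higher in fasted arrays (log2 fold change 3.52, SE 0.58, adjusted p = 2.07e-04), with a wide spread among them: 6.34 ± 1.86 against 2.82 ± 0.23 in fed arrays (SD, n = 8). Within the fasted group its level followed the mean of the liver transcripts, with Pearson's r = 0.961 (exact permutation p = 2.98e-04, n = 8) and Spearman's rho = 0.929 (exact permutation p = 0.00223). Without the 2 arrays farthest from the median liver mean, r was 0.924. Within the fed group r was -0.100. Of 9 genes set against the liver mean in the fasted arrays, all chosen after the data were seen, Cyp4a14 and Apoa4 passed a Benjamini-Hochberg adjustment (both adjusted p = 0.00179 by exact permutation, n = 8), and Pdk4, Vnn1 and Zim1 did not (r = 0.627, 0.185 and 0.272). Without the 2 arrays farthest from the median liver mean, r was 0.551 for Pdk4, 0.189 for Vnn1 and 0.887 for Zim1, so the low r of Zim1 rested on those 2 arrays. They were fasted replicates 5 and 3, with the lowest liver means of the fasted group (4.76 and 4.79). Zim1 stood at 8.86 and 9.22 in them, against at most 4.91 in fed arrays, so its rise was also present where the liver mean was low.

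**Figure D2:**
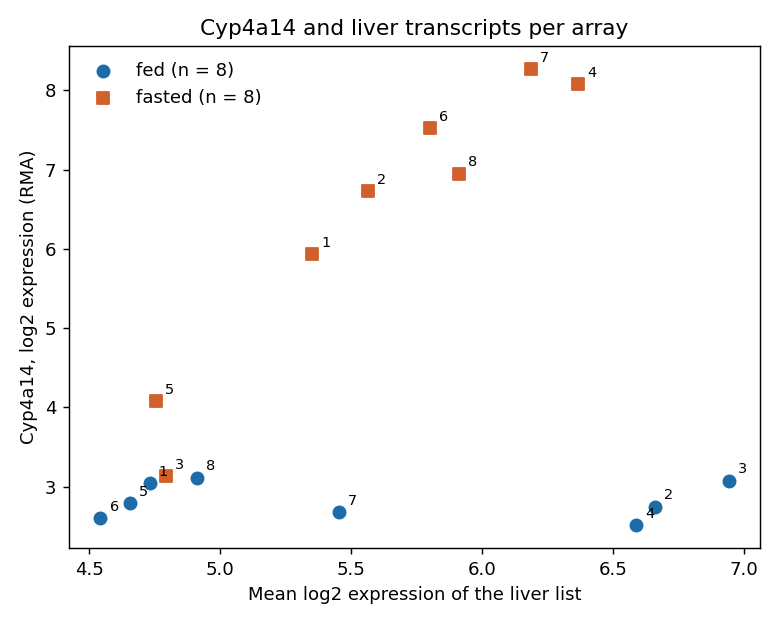
Cyp4a14 on the vertical axis against the mean of 19 liver transcripts on the horizontal axis, both as log2 expression, with each point an array numbered by its replicate. Among the fasted arrays (squares) Cyp4a14 ranges from 3.13 to 8.27 and increases with the liver mean (r = 0.961), and the fed arrays (circles) stay between 2.51 and 3.11.

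The largest fall was that of Pnpla3, a lipid droplet protein that follows feeding, which dropped from 9.66 ± 0.29 to 5.88 ± 0.72, a 13.8-fold difference (SD, n = 8; limma adjusted p = 4.23e-09). Cdsn, Rgs7bp and Lrrc39 were 8.88-fold, 7.19-fold and 6.51-fold lower. Gpt, an alanine aminotransferase, was 6.46-fold lower, and the lactate receptor Hcar1 5.67-fold. The mitochondrial dicarboxylate carrier Slc25a10 was lower by 5.66-fold, Cldn22 5.52-fold, Dgat2, which makes triglyceride from diglyceride, 5.10-fold, and Trabd2b 4.57-fold. Asb12 fell by 2.85 on the log2 scale, but its other probe set gave -0.11 (adjusted p = 0.387). Leptin (Lep) fell 3.81-fold, from 11.30 ± 0.39 to 9.37 ± 0.89.

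**Figure D3:**
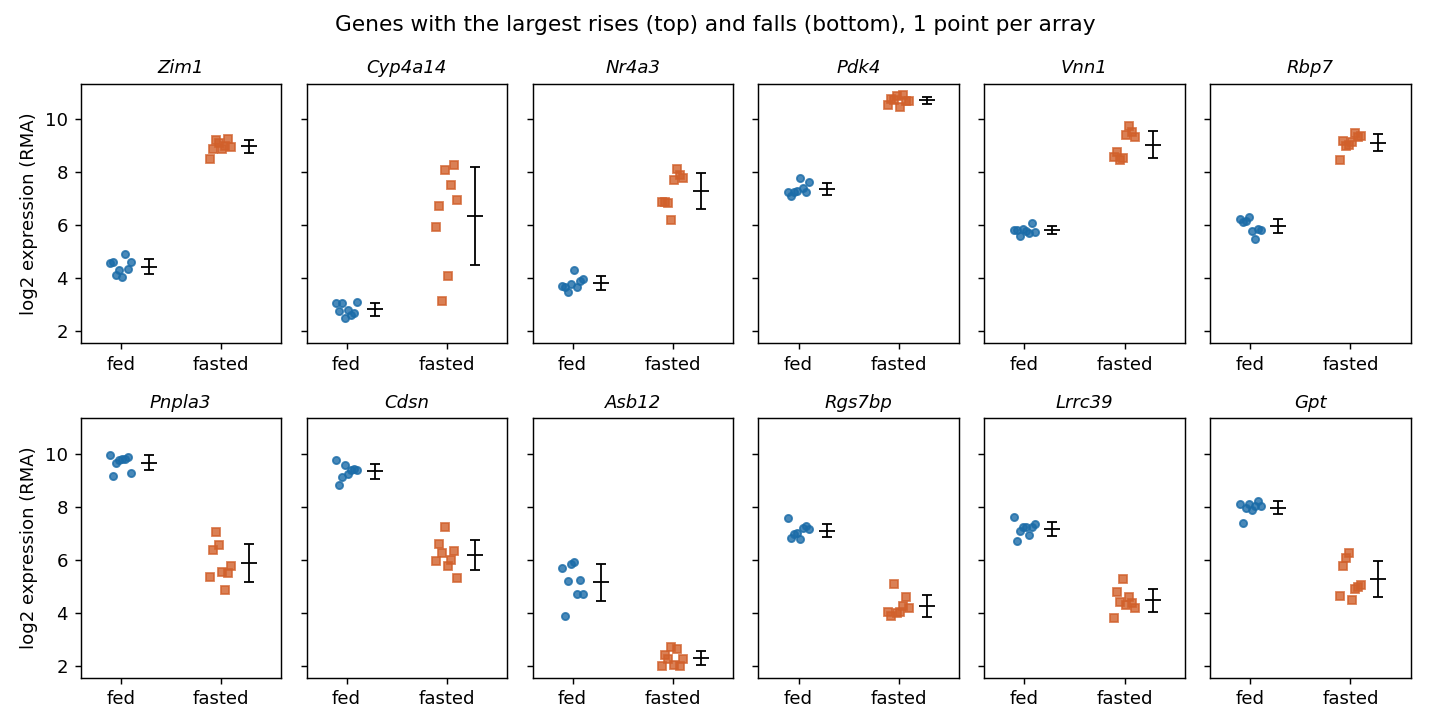
Log2 expression of the 6 genes with the largest rises (top row) and the 6 with the largest falls (bottom row), with 1 point per array and the group mean ± SD beside the points. The groups do not overlap in any of the 12 genes, and the fasted arrays spread most for Cyp4a14 (SD 1.86).

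Over all genes, 4251 of 22180 (19.2%) were called, 1883 higher and 2368 lower in fasted arrays. Of these, 590 rose and 668 fell by at least 1.5-fold, and 179 rose and 166 fell by at least 2-fold. In 1434 called genes the groups did not overlap, against a chance share of 0.0155% of genes. Higher calls made up 44.3% of the total, and 54.7% of 3817 calls when the array medians were subtracted first. Without fed replicates 2 and 3 and fasted replicate 7, 3886 genes were called and 3512 of the 4251 (82.6%) kept their call.

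Genes that build fatty acids and cholesterol fell together. Of 20 measured genes of fatty acid synthesis, 14 fell, 1 rose and 5 were not called (15 fell and 1 rose when adjusted over the list alone; camera adjusted p = 4.23e-13, and adjusted p = 0.0214 with an estimated correlation). Fasn, the fatty acid synthase, fell 4.76-fold, Thrsp 4.43-fold and Srebf1, the transcription factor that drives these genes, 3.94-fold. The member that rose was Acacb, by 1.58 on the log2 scale (SE 0.16), named after its value was seen; it encodes the acetyl-CoA carboxylase at mitochondria. Scd1, the stearoyl-CoA desaturase, stood at 12.23 ± 0.10 in fed and 12.31 ± 0.11 in fasted arrays (SD, n = 8; limma adjusted p = 0.482). Of 19 genes of cholesterol synthesis, 16 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 4.85e-17, and adjusted p = 0.00306 with an estimated correlation). Insig1 fell 3.48-fold, Fdps 2.52-fold and Sc5d 2.38-fold. Triglyceride synthesis was divided, with 4 of 18 genes higher and 6 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.721). Dgat2 and the glycerol phosphate dehydrogenase Gpd1 fell 5.10-fold and 4.38-fold, and the fatty acid transporter Slc27a1 rose 2.96-fold. Lpin1, a phosphatidate phosphatase, rose 1.31-fold.

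**Figure D4:**
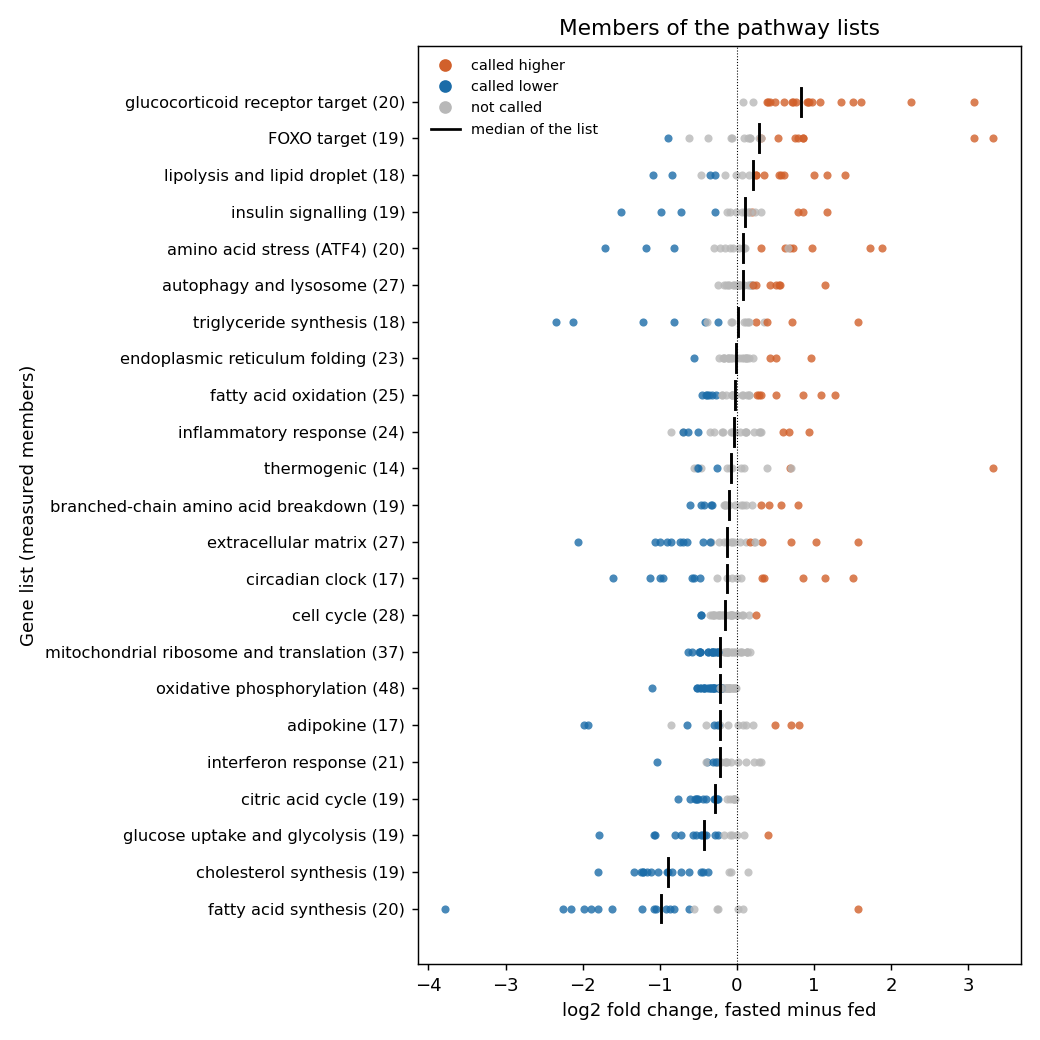
Log2 fold change (fasted minus fed) of each measured member of the 23 pathway lists, with points coloured by whether the gene was called higher, lower or not called, and a bar at the list's median. The medians lie between -0.98 for fatty acid synthesis and 0.84 for glucocorticoid receptor targets.

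Some genes of glucose use and of mitochondria fell, by smaller steps, and the calls of these 4 lists were lost with an estimated correlation. Of 19 genes of glucose uptake and glycolysis, 13 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 3.05e-08, but adjusted p = 0.0526 with an estimated correlation). The insulin-responsive glucose transporter Slc2a4 fell 3.46-fold, Hk2, a hexokinase, 2.11-fold and Tpi1 2.08-fold. The member that rose was the transporter Slc2a1, by 0.40 (SE 0.12), named after its value was seen. Of 19 citric acid cycle genes 13 fell and none rose (13 adjusted over the list alone; camera adjusted p = 3.31e-08, and adjusted p = 0.115 with an estimated correlation), led by Idh3a, Cs and Sdhd at 1.70-fold, 1.52-fold and 1.46-fold. Of 48 genes of oxidative phosphorylation 23 fell and none rose (29 adjusted over the list alone; camera adjusted p = 7.26e-11, and adjusted p = 0.160 with an estimated correlation), with Ndufb3 2.15-fold lower and Ndufs1 and Cyc1 each 1.43-fold lower. The mitochondrial ribosome and translation list had 16 of 37 genes lower and none higher (18 lower adjusted over the list alone; camera adjusted p = 1.13e-05, and adjusted p = 0.220 with an estimated correlation), among them Mrpl34 at 1.55-fold and Mrpl18 at 1.40-fold.

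The list most clearly raised was that of glucocorticoid receptor targets. Of its 20 members 18 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 9.17e-20, and adjusted p = 0.00306 with an estimated correlation). Ddit4 rose 8.46-fold, the kinase Sgk1 4.79-fold and Cebpd 3.07-fold. Of 19 FOXO targets 8 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 7.51e-06, and adjusted p = 0.0526 with an estimated correlation), with Pdk4 and Ddit4 in front and Irs2, an insulin receptor substrate, 1.80-fold higher, while Sesn3 fell 1.85-fold. In the autophagy and lysosome list 7 of 27 genes rose and none fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00602, and adjusted p = 0.217 with an estimated correlation), led by Gabarapl1 at 2.22-fold, Wipi1 at 1.48-fold and Ulk1, the kinase that starts autophagy, at 1.47-fold.

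Lipolysis and lipid droplet genes moved both ways, with 9 of 18 higher and 4 lower (9 and 5 adjusted over the list alone). The droplet proteins Plin5 and Hilpda rose 2.65-fold and 2.25-fold, the triglyceride lipase Pnpla2 rose 1.52-fold, and G0s2, which inhibits that lipase, fell 2.12-fold. The hormone-sensitive lipase Lipe had a log2 fold change of -0.0093 (SE 0.055, adjusted p = 0.947). The other members that fell were Plin1, Mgll and Bscl2, by 0.84, 0.35 and 0.28 on the log2 scale, named after their values were seen. The list was called higher (camera adjusted p = 0.0323), but not with an estimated correlation (adjusted p = 0.452), after subtraction of array medians (0.0571), with the filter on linear values (0.0511), without fed replicate 2 (0.0676), without fasted replicate 8 (0.0546) or without the 3 arrays that stood apart (0.0920). Fatty acid oxidation had 7 of 25 genes higher and 6 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.721). Ehhadh, of peroxisomal oxidation, rose 2.43-fold, the thioesterase Acot1 2.14-fold and Ucp3 1.81-fold, while Cpt1a, which admits fatty acids to mitochondria, had a log2 fold change of 0.16 (SE 0.083, adjusted p = 0.228). Acot1 correlated with the liver mean within fasted arrays at r = 0.799 (adjusted p = 0.0591 by exact permutation, n = 8).

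Extracellular matrix genes included 10 of 27 lower and 5 higher (11 and 5 adjusted over the list alone). Col15a1, of the basement membrane zone, fell 4.16-fold and Nid2 2.08-fold, whereas Lox, which cross-links collagen, rose 2.97-fold. The other 4 that rose, named after their values were seen, were Thbs1, Postn, Col4a1 and Lamb1, by 1.03, 0.70, 0.32 and 0.18 on the log2 scale. The list was called lower (camera adjusted p = 0.0308), but not with an estimated correlation (adjusted p = 0.632), with either filter on dim genes (0.205 and 0.200), without shared genes (0.0642), or without fasted replicate 8 (0.0546), fed replicate 4 (0.0652) or fed replicate 6 (0.0912). Of 28 cell cycle genes 2 fell, Mcm5 by 1.38-fold and Tyms by 1.38-fold, and Mcm7 rose by 0.25 (SE 0.082), a call lost without any 1 of fasted replicates 1, 3, 5, 6, 7 and 8 and fed replicates 1, 2, 4, 5 and 7 (adjusted p = 0.0527 to 0.0805) (2 lower and 0 higher adjusted over the list alone). The cell cycle list was called lower (camera adjusted p = 0.0265), but not with an estimated correlation (adjusted p = 0.325), with the filters on dim genes (0.268 and 0.237), without fed replicate 6 (0.0801) or without fasted replicate 8 (0.0515). Of 21 interferon response genes 4 fell and none rose (5 lower adjusted over the list alone; camera adjusted p = 0.0231, and adjusted p = 0.444 with an estimated correlation, 0.182 and 0.177 with the filters on dim genes). Gbp3 fell 2.04-fold and Ifi35 1.31-fold, with the other probe set of Ifi35 at -0.18 (adjusted p = 0.438). The others were Psmb9, whose call was lost without any 1 of 12 arrays (all but fed replicates 1 and 4 and fasted replicates 2 and 8; adjusted p = 0.0565 to 0.0980), and Xaf1, named after its value was seen.

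The remaining pathway lists were not called by camera, though many of their members changed. The rotation test fry did call some of them. These were the thermogenic list as higher (fry adjusted p = 2.34e-06), the circadian clock list as lower (0.0385) and the insulin signalling list as higher (0.0487). In the circadian clock list (camera adjusted p = 0.318) 5 of 17 genes rose and 7 fell, with the same counts adjusted over the list alone. Per1 and Npas2 rose 2.83-fold and 2.22-fold, and Dbp fell 3.04-fold and Nr1d1 fell by 0.58 on the log2 scale (SE 0.11). In the amino acid stress list (camera adjusted p = 0.173) 7 of 20 genes rose and 3 fell (8 and 3 adjusted over the list alone). Chac1, which breaks down glutathione, and Sesn2 rose 3.69-fold and 3.30-fold. The 3 that fell were the serine synthesis enzymes Psph, 3.27-fold lower, Psat1 and Phgdh, the latter pair lower by 1.18 and 0.82 on the log2 scale and named after their values were seen. In the insulin signalling list (camera adjusted p = 0.318) 4 of 19 rose and 4 fell, as they did when adjusted over the list alone. The adaptor Grb10 rose 2.25-fold, and the regulatory subunit Pik3r1 and the adaptor Grb14 fell 2.85-fold and 1.97-fold. Among 17 adipokines (camera adjusted p = 0.434) 3 rose and 5 fell (3 and 7 adjusted over the list alone). Vegfa rose 1.75-fold and Angptl4, which inhibits lipoprotein lipase, 1.41-fold. Angptl8 fell 3.94-fold, and adiponectin (Adipoq) had a log2 fold change of -0.12 (SE 0.067, adjusted p = 0.284). Of 19 genes of branched-chain amino acid breakdown 4 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.744), with Ppm1k 1.73-fold higher and Pcca 1.53-fold lower. Of 23 genes of endoplasmic reticulum folding 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.719). Derl3 rose 1.94-fold, and Edem1 fell 1.47-fold. The thermogenic list (camera adjusted p = 0.713) had 2 of 14 higher, Pdk4 and Fgf21, the latter by 1.61-fold, and 3 lower, among them Cox7a1 at 1.43-fold (2 and 4 adjusted over the list alone). Fgf21 and Cox7a1 were dim and did not pass the filter on linear values. Pdk4 rose by 3.32 on the log2 scale while the list's median was -0.076. The fry call of this list therefore does not show a rise of most members. The inflammatory list (camera adjusted p = 0.916) had 3 of 24 higher and 3 lower (3 and 4 adjusted over the list alone), with Nfkbia 1.91-fold higher and Nos2 1.62-fold lower. The call of Ccl3 was lost without fasted replicates 6, 7 or 8 or fed replicate 6 (adjusted p = 0.0524 to 0.0556). The median and the mean log2 fold change differed in sign for triglyceride synthesis (0.014 and -0.22), fatty acid oxidation (-0.028 and 0.090), endoplasmic reticulum folding (-0.017 and 0.044) and the thermogenic list (-0.076 and 0.19). Members of these small counts outside the rule are given here, named after their values were seen. Cry1, Arntl and Rora were the other clock genes that rose. In insulin signalling they were Insr and Pik3ca (higher) and Tbc1d4 and Rptor (lower). Among adipokines they were Nrg4 (higher) and Retn, Rbp4 and Apln (lower). In branched-chain breakdown they were Hibch and Bckdhb (higher) and Mccc1, Bcat2, Bckdk and Acad8 (lower). Esrra and Prdm16 fell in the thermogenic list, and Herpud1 rose in the folding list. Vcam1 rose and Saa3 and Tnf fell in the inflammatory list. Aqp7 and Pck1 rose in triglyceride synthesis. In the panel, Ppargc1a, Ppara, Pparg and Lpl were not called, with log2 fold changes of 0.39 (SE 0.19), 0.056 (SE 0.079), 0.0072 (SE 0.11) and 0.092 (SE 0.067).

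Among the markers of the cells that fat holds, the endothelial list was the 1 of 14 tested that was called. Of its 14 genes 5 rose and none fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0216), with the receptor Eng 1.70-fold and Sox17 1.52-fold higher. That call was lost with an estimated correlation (adjusted p = 0.789), array weights (0.0521), either filter on dim genes (0.0570 and 0.0621), without fed replicate 2 (0.0689), 3 (0.0884) or 5 (0.0667), without fasted replicate 3 (0.0619) and without the 3 arrays that stood apart (0.158). Macrophage markers were divided, with 6 of 19 higher and 3 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.241). The lysosomal protein Cd68 rose 1.85-fold and the protease Lgmn 1.72-fold. Of 16 adipocyte markers 2 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.241), led by the falls of Gpd1 and Lep given above. The rotation test fry called the adipocyte list lower (fry adjusted p = 0.00938). In the fibroblast and preadipocyte list 4 of 14 fell and none rose (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.241), among them Col3a1 at 1.66-fold, with Lum lower by a log2 fold change of -0.68. Smooth muscle and pericyte markers included 1 of 12 higher, Acta2 at 1.74-fold, and 3 lower, with Cspg4 2.11-fold lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.269). Of 13 T and natural killer cell markers 1 rose, Il7r by 1.99-fold, and 2 fell, among them Gzma by 1.54-fold, as they did when adjusted over the list alone (camera adjusted p = 0.683). Besides Acta1 and Myl1, the other 10 of 12 skeletal muscle markers were not called (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.683). The median and mean of skeletal muscle markers differed in sign (-0.077 and 0.054), as did those of B and plasma cells (0.020 and -0.021). Other members of these small counts were named after their values were seen. Flt1, Pecam1 and Tek rose among endothelial markers, and Itgax, Mrc1 and Timd4 fell among macrophage markers. The rest were Plin4 and Cidec (adipocyte, higher), Cd248 and Cd34 (fibroblast, lower), Rgs5 and Notch3 (smooth muscle, lower) and Ncr1 (natural killer cell, lower).

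The rest of the cell type lists held few calls. Of 10 mast cell markers 2 rose, Hdc by 0.46 and Tpsab1 by 0.35 on the log2 scale (2 adjusted over the list alone; camera adjusted p = 0.241), and of 13 mesothelial markers 1 fell, Krt19 by 0.55 (0 adjusted over the list alone; 2 at an unadjusted limma p under 0.05; camera adjusted p = 0.241). Of 19 epididymal markers 1 fell, Spint4 by 0.20 (0 adjusted over the list alone; 2 at an unadjusted limma p under 0.05; camera adjusted p = 0.522). Each of these 4 calls was lost without some single arrays. Hdc lost it without fasted replicates 1, 5 or 8 or fed replicates 4, 7 or 8 (adjusted p = 0.0556 to 0.0646), and Tpsab1 without fasted replicates 1, 3 or 5 or fed replicates 4 or 5 (0.0525 to 0.0607). Spint4 lost it without fasted replicates 6 or 7 or fed replicates 3 or 6 (0.0535 to 0.0602), and Krt19 without any array but fasted replicates 1, 2 and 5 and fed replicate 6 (0.0532 to 0.0998). No marker was called by limma among 10 of neutrophils (0 at an unadjusted p under 0.05; camera adjusted p = 0.552), 11 of B and plasma cells (1; 0.873), 7 of Schwann cells and nerve (2; 0.683), 13 of testis germ cells (1; 0.873) and the 2 measured of red blood cells (0), and the counts adjusted over these lists alone were also 0. In 2 of these lists a marker passed without 1 array. These were Tnfrsf17 of plasma cells at -0.50 without fasted replicate 1 (adjusted p = 0.0368), and Pmp2 of Schwann cells at 0.38 without fasted replicate 4 (0.0489).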

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

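All tests of explanations in this part were chosen after the patterns were seen. The 2 tests that use correlations with liver transcripts were added after the first liver test, on fed replicate 3, had fallen short of its bound.

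In each group of 8, the gap of the highest or lowest array to its nearest neighbour was set against the range of the group for 120 named genes and 37 list means. Of 314 groups 19 passed Dixon's 95% limit, where chance gives about 1 in 20, and 6 of the 19 were in fed replicate 2. That array was low for Mrps22 (gap over range 0.793; 5.56 against a median of 6.26 in the other fed arrays), Irf4 (0.649), Gpt (0.624) and Adipoq (0.557), and high for the means of the epididymal (0.612) and B and plasma cell lists (0.602). Fed replicate 1 was high for Slc4a1 (0.585) and Lpin1 (0.537), fed replicate 3 for the mean of fatty acid oxidation (0.581) and fed replicate 6 for the mean of Schwann cell and nerve markers (0.531). Fasted replicate 1 was high for the mean of fibroblast and preadipocyte markers (0.655), Pmp2 (0.591) and Dbp (0.534) and low for Sdhd (0.579). Fasted replicate 2 was low for Angptl4 (0.574) and high for Fdps (0.540), fasted replicate 4 was high for Tpi1 (0.691) and Ppara (0.563), and fasted replicate 5 was high for Ldhc (0.733). Each called gene among these kept its call without any 1 array.

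Fed replicate 2 and fasted replicate 7 shared 357 genes that lay over 1 on the log2 scale from the median of their group in the same direction, led by Mmp7, higher by 5.77 and 5.30, and Cuzd1, higher by 5.75 and 4.94, and the residuals of the 2 arrays correlated at r = 0.620 across genes, which are not independent replicates (next highest pair 0.218). A shift of all genes by the same amount is argued against, because it would leave the residual correlation across genes unchanged. That correlation was 0.620 here, against at most 0.218 in other pairs. An array-wide shift through RNA quality or normalization that differs between genes stays open. All 357 genes (100%) were higher, which met the bound written against such a shift. An upward shift would also give that share, a limit recognised after the value was seen, so the share decides nothing. The 2 arrays had the highest medians over all genes (4.35 and 4.28, against at most 4.22 in the others). The 1.44 (SE 0.20) by which the cilia genes exceeded all genes decides nothing. The normalization holds the median excess of all genes near 0 (-0.033 and -0.015), and the cilia list was chosen for being high here. Of 25 motile cilia genes, 72.0% had these as their 2 highest arrays, where chance gives 0.833%; this fell just short of the 75% set for ciliated duct tissue taken with the fat, which stays open. Principal cells of the epididymis also stay open, because the median excess of 19 epididymal markers was -0.0042 with an SE of 0.245. That SE was widened by Adam7 and Lcn2, named after their values were seen. Adam7 was higher by 3.59 in fed replicate 2 and 2.22 in fasted replicate 7, and Lcn2 by 2.88 and 1.97. The excesses of the other markers lay between -0.50 and 0.66. The arrays are 1 fed and 1 fasted, so the design offers no biological explanation and none was tested.

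The liver transcripts moved as a block: over 171 pairs of the 19 liver genes, the median correlation of deviations from the group means across the 16 arrays was 0.905, as liver tissue or liver RNA in the samples would give, although only 63.2% of the genes were highest in fed replicate 3, short of the 75% set for that array alone, and 10 of the 19 had fed replicates 2 and 3 as their 2 highest arrays. Albumin (Alb) was higher by 2.13 in fed replicate 2 and 1.99 in fed replicate 3, and 1 list member, Cyp2e1, is also abundant in fat, at a mean of 12.20. An acute-phase response within the fat is argued against by 8 liver enzymes outside that response, whose median excess in fed replicate 3 was 1.85 (SE 0.316). All 8 belong to the liver list, which was chosen after the data were seen, so they are not independent of the pattern. Cyp2e1, with an excess of 0.49, is 1 of them. For Cyp4a14, liver RNA in the fasted samples is a candidate source: its r with the liver mean was 0.961 within fasted arrays, and the 2 fasted arrays with the lowest liver means, replicates 5 and 3, stood at 4.08 and 3.13 against at most 3.11 in fed arrays. With the liver mean as a covariate the log2 fold change kept 99.3% of its size, at 3.49, but the liver mean differed by only 0.031 between the groups, so that fit could hardly have moved the difference whatever its source, and a response of the fat itself to fasting was not tested and stays open.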

How the results depend on the processing

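Leaving out 3 arrays and the liver covariate were chosen after seeing the data. No named gene or list reversed its direction past a threshold in any alternative. The balance of all calls did turn with subtraction of array medians, to 2086 higher and 1731 lower, against 1883 higher and 2368 lower in the main fit. The count of 4251 genes stayed between 3823 and 4265 without any 1 array (1673 to 1910 higher, 2112 to 2445 lower), and between 3817 and 4756 under the other normalizations, filters, variance models, probe set choices, the exact rank sum test, the liver covariate and without the 3 arrays. By construction, stricter limits gave fewer: 2766 genes (1214 higher, 1552 lower) at an adjusted p under 0.01, 1598 (735 and 863) under 0.001, and 1258 (590 and 668) with at least a 1.5-fold change. The replicate numbers did not pair the samples: residuals of same-numbered arrays correlated at -0.216 to 0.218, over 0.1 in 2 of 8 pairs, and 3 of 16 arrays correlated best with their own number. With the replicate number as a block, 3829 genes (1682 and 2147), 12 pathway lists and 1 cell type list were called; the list lost was extracellular matrix (adjusted p = 0.0500035), and Ccl3, Hdc, Psmb9 and Spint4 lost their calls. Pathway lists numbered 10 to 13 without any 1 array, 9 and 10 with the filters on dim genes, 16 with fry, and 3 instead of 13 with an estimated correlation (7 at an unadjusted p under 0.05), since larger correlations within lists widen that test. The 1 cell type list became 0 with an estimated correlation (0 at an unadjusted camera p under 0.05), with either filter on dim genes (1 each), with array weights (2) and without the 3 arrays (3), and 2 with fry; without any 1 array it was 0 to 1. The cause was not tested. Of the 120 named genes, 114 kept their side of the threshold without the 3 arrays, 118 with cyclic loess, 117 with median subtraction and 118 with the liver covariate. Dim signal limits the rest: 10832 genes (48.8%) passed the filter on linear values, and 500 of the 4251 called genes did not. Of the 120 named genes, 106 passed it. The called named genes that failed it were Acot1, Asb12, Cox7a1, Cyp4a14, Derl3, Fgf21, Gzma, Hdc, Spint4 and Tpsab1. Their fold changes rest partly or wholly on dim values.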

Other observations

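In this part, the comparisons of Peg3 with Zim1 and with the other imprinted genes by size were chosen after the results were seen.

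Several imprinted genes, which are expressed from 1 parental copy, changed with fasting, all named after their values were seen. Besides Zim1, its neighbour Peg3 rose by 2.19 on the log2 scale (SE 0.093, limma adjusted p = 2.43e-11). Of 34 other imprinted genes measured, 3 rose and 9 fell: Grb10, Peg10 and Cdkn1c rose by 1.17, 0.98 and 0.83, and among those that fell, Nnat, Ndn and Plagl1 fell by 1.31, 0.83 and 0.47.

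The joint rise of Zim1 and Peg3 was set against 3 explanations. Peg3 signal on the Zim1 probes is argued against, since the log2 fold change of Zim1 exceeded that of Peg3 by 2.34 (SE 0.084), unless the Peg3 probe set understates its change. A rise of imprinted genes as a group, of the size seen in Peg3, is argued against, since Peg3 exceeded the median of the 34 others by 2.22, against an SD of 0.46 among them and a largest rise of 1.17, while a small rise of the group stays open, with a median of -0.037 (SE 0.099) that missed the bound set beforehand and p = 0.389 by camera with an estimated correlation. A rise of all genes around the locus cannot be told apart either: 0 of the 10 measured genes nearest to Peg3 were called higher by limma (1 at an unadjusted p under 0.05), which met the bound of at most 1 set beforehand, but 0 of the 10 passed the filter on dim genes and their highest mean was 2.86, a limit recognised after the value was seen, so the test decides nothing. Both genes rose in the fasted arrays in the limma comparison, by 4.53 (SE 0.125) for Zim1 and 2.19 (SE 0.093) for Peg3 on the log2 scale. Why they rose together was not tested further and stays open.

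The 16 arrays were also divided into 8 and 8 in 100 ways, the real one included. Only 1 of the 100, the real division, called as many as 4251 genes. The highest of the others was 2123, in a division with 7 of the 8 fasted arrays on 1 side, and the next highest was 106. A share of 1 in 100 is the smallest that 100 divisions can give. It met the bound set beforehand, so chance is argued against for the gene count. For the 13 pathway lists 3 of the 100 divisions, the real one included, called as many, with 14 the highest of the others and 6 their median. That share met the bound set beforehand for excluding chance. The bound is weak here, because the preset correlation called lists in many arbitrary divisions and the highest exceeded the real count. Divisions with unequal numbers of fasted arrays on their sides also held part of the fasting difference. Those that called 13 and 14 lists had 3 and 5 fasted arrays on 1 side. With 4 fasted arrays on each side, the highest count was 8. Since many divisions were not free of the fasting difference, the number of lists alone does not decide on chance. For the 1 cell type list 88 of the 100 divisions called as many, with 7 the highest of the others, so chance cannot be excluded.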
